A study of Caenorhabditis elegans with 2 samples.

How the data were processed

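ChIP-seq was performed on 2 biological replicates of 1 transgenic strain, as whole young adults of mixed sex with CEH-79 tagged with GFP and FLAG and an antibody against GFP, per the labels. Chromatin was sheared by sonication, per the labels. Per the notes deposited with the files, peaks were called on the alignment of each replicate and on the pooled alignments against one control alignment, and the optimal list was derived from the replicate lists and the pooled list by the irreproducible discovery rate. The aligner, peak caller and their versions are not given in the sources used here. The deposited signal of a peak is the authors' own value for it, and was used to describe, rank and filter peaks within a list. Between the replicate lists only the ranks of the signal were compared, in the correlation and the discovery rate fit. The deposited -log10 q of a peak reaches a common maximum in 452 pooled peaks, and was used only as an alternative score for the replicate correlation. The lists hold no read counts, so depth is unknown and the precision given is that of counts of peaks. Signal tracks were not used here.

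Lists in ce11 and ce10 were read as deposited. Annotation came from Ensembl release 115 of WBcel235, which has the coordinates of ce11, and sequence from the RefSeq assembly. Annotation of ce10 was not used here, so ce10 entered only counts, chromosomes and the comparison of replicates. Coordinates are 1-based. The tRNA isotypes came from the RefSeq annotation, which paired 607 of 612 tRNA genes. Long noncoding RNA genes were those the annotation calls long intergenic.

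Before the data were examined, the tests, the 34 gene lists, 37 sequence words and the alternatives were fixed. The comparison by position in gene models was not among the fixed tests. Optimal summits were compared with those of the other pooled candidates by two-sided Fisher's exact tests for promoter windows (1000 bp upstream to 200 bp downstream of a protein-coding start site), the X chromosome and 7 noncoding classes within 500 bp. Gene lists needed at least 5 members in the background, and p-values were adjusted by the Benjamini-Hochberg method over the classes, the lists or the words. Words of 6 bases were tested by two-sided exact McNemar tests between the 101 bp summit window and flanks centred 275 bp to each side, with the same number of word starts. Replicate peaks were matched through the pooled list by at least 1 bp, and a Gaussian copula mixture was fitted by expectation maximization for the irreproducible discovery rate. The interval of the replicate correlation came from 2000 bootstrap draws over peaks. The genes named were ceh-79 and unc-119, the promoter genes or nearest start sites of the 25 strongest optimal peaks, up to 6 members of each list that passed, and up to 4 of other lists mentioned, highest signal first. The 10 words with the lowest p were named too. From those 25 peaks the text names the ones it describes.

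Alternatives covered other promoter windows, distances, word windows, matching rules, thresholds and backgrounds, the ce10 lists, the 283 strongest optimal peaks, and each replicate alone. Without one replicate, the 566 strongest candidates of the other stood in for the optimal peaks. Alternatives that left out peaks near tRNA, snoRNA and snRNA genes, added the annotation's unspecified noncoding class, or set noncoding classes against the 2830 strongest other candidates were chosen after seeing the data. Gene copies were compared by edit distance over whole genes, and a gene was called distinct where no other tRNA or snoRNA gene reached 90% identity.

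The tests were tested on simulated data. With no enriched list, 1% of 100 draws over 7186 genes called any list. The ribosomal protein list, made 5 times as likely, was recovered in 78% of draws, and recovery of smaller lists was not simulated. With summit and flank exchanged at random over 566 peaks, a mean of 0 words was called in 20 draws, and a word placed in 30% of summits was recovered in 100% of them. In the data GTTCGA was at 13.6% of summits and TAATTA at 1.41%. Recovery of words placed in fewer summits was not simulated, so the power for such words is unknown. Of 28000 simulated peaks, 700 were reproducible, and the discovery rate fit called 683 with 5.56% irreproducible. Those simulated reproducible peaks were few and well separated from the rest. The fit to the 14848 matched peaks of the data put 27.6% in a reproducible component with a mean of 1.13 and an SD of 1.16, which overlaps the other component. The simulation therefore does not give the error rate of the calls in the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and edlib 1.3.9.post1.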

Results

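Binding of CEH-79, a homeobox transcription factor of Caenorhabditis elegans, was profiled by ChIP-seq in whole young adult worms of mixed sex. The worms carried an integrated transgene encoding CEH-79 with a C-terminal GFP-FLAG tag, and chromatin was precipitated with an antibody against GFP. They were collected 66 hours after synchronization at the starved first larval stage. The series held 1 group of 2 biological replicates, so the question it addressed was where the tagged protein was recovered along the genome, and no contrast between conditions was possible. The deposited values were peaks with a signal and not reads, so the read depth of each replicate is unknown. The candidate lists held 30000 peaks for replicate 1, 29624 for replicate 2 and 30000 for the pooled alignments in the ce11 assembly, whose coordinates are used throughout. The authors' optimal list, thresholded on the irreproducible discovery rate, held 566 peaks. Intervals are at 95%. Those of shares are exact binomial intervals over peaks or genes that cover counting error only, and neighbouring peaks are not independent. Some optimal peaks overlap one another, such as those ranked 20 and 185 by pooled signal, and the tests counted each of them.

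The 566 optimal peaks were the 566 pooled candidates with the highest signal, which ran from 86.5 to 409, against a median of 32.6 over all pooled candidates. Their median width was 424 bp. Chromosome III held 113 of them, X 105, IV 93, I 91, II 83 and V 81. The strongest peak (V, 12303481 to 12303776, signal 409) lay in an intron of frm-7 beside the snoRNA genes C51F7.3 and C51F7.4, and ranked 1 in both replicates. The peak at V, 8500413 to 8500680 (signal 361), lay in an intron of pxn-1 beside the snoRNA gene ZK994.7 and ranked 2 in both. The peak at I, 13463805 to 13464081 (signal 344), lay in an intron of ints-8 beside rpr-1, the gene for the RNA of RNase P, and ranked 3 in both. The next peak (III, 3867437 to 3867676, signal 294) was intergenic, with its summit 289 bp upstream of the start of rpl-3, which encodes a protein of the large ribosomal subunit. A peak in an intron of mdt-26, a Mediator subunit gene, followed at II, 5661629 to 5662061 (signal 279). The noncoding neighbours and host genes of these peaks were named after their values were seen.

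Further down the 25 strongest peaks, a peak upstream of egg-5 (I, 4172186 to 4172521, signal 253) lay beside sls-2.4, a spliced leader RNA gene. A peak at II, 11759342 to 11759606 (signal 238), lay between the neighbouring genes F44E5.4 and F44E5.5. A peak at I, 14759383 to 14759604 (signal 220), served the promoter windows of rps-26 and tmem-107 and lay beside the snoRNA gene F39B2.14. The promoter windows of dnj-13 (signal 209), set-16 and drr-2 (signal 200.9 for their shared peak), tasp-1 (signal 224), sre-23 (signal 237) and kel-3 (signal 197) also held peaks of this set. Of the 25 strongest peaks, 15 (60%, interval 38.7 to 78.9%) had a summit within 500 bp of a tRNA, snoRNA or snRNA gene.

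How far the replicates repeated one another was examined without the authors' threshold. Of the 566 strongest candidates of replicate 1, 265 (46.8%, interval 42.6 to 51.03%) overlapped one of the 566 strongest of replicate 2 by at least 1 bp. Random ranks within replicate 2 gave a mean of 13.9 and a maximum of 28 over 1000 draws. Both replicates were called against one control alignment, and random ranks do not keep any agreement that this creates. Each optimal peak overlapped a candidate in replicate 1, and 565 overlapped one in replicate 2. Among optimal peaks, 271 lay among the 566 strongest of both replicates and 43 among those of neither. Across the 565 peaks with both values, the signals had a Spearman correlation of 0.218 (bootstrap interval 0.126 to 0.298). Over all 14848 pooled candidates matched in both replicates it was 0.334. These correlations are across peaks, which are not independent replicates. Optimal peaks also had the highest pooled signal, and choosing peaks by a value that combines both replicates can lower the correlation among them. The correlation over optimal peaks therefore does not measure agreement alone. It was -0.165 with the capped -log10 q in place of the signal. A separate fit of the irreproducible discovery rate to 14848 peaks matched in both replicates called 1177 at a threshold of 0.05, of which 531 were optimal. At a threshold of 0.01 it called 601.

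Optimal summits lay near genes for short noncoding RNAs far more often than other candidates. Within 500 bp of a tRNA gene lay 19.8% of the 566 optimal summits (interval 16.6 to 23.3%), against 464 of 29434 other pooled candidates (1.58%), an odds ratio of 15.4. For snoRNA genes, which encode guides of RNA modification, the values were 53 optimal summits (9.36%) and 225 others (0.764%), an odds ratio of 13.4. For snRNA genes they were 17 (3.004%) and 59 (0.2004%), an odds ratio of 15.4. The annotation's snRNA class includes spliced leader RNA genes such as sls-2.4. The adjusted p over 7 classes was 2.92e-79 for tRNA, 1.05e-36 for snoRNA and 1.22e-13 for snRNA genes by two-sided Fisher's exact tests. Against the 2830 strongest other candidates, a background chosen after the data were seen, the odds ratios were 3.59 for tRNA, 6.12 for snoRNA and 5.12 for snRNA genes. Without replicate 1 the odds ratio for snRNA genes was 8.21 (11 summits, adjusted p = 9.50e-07, Fisher's exact test). Among the other classes, 5 optimal summits lay near miRNA genes (adjusted p = 0.154, Fisher's exact test), 5 near long intergenic noncoding RNA genes (adjusted p = 0.154, Fisher's exact test) and 17 near pseudogenes (adjusted p = 0.846, Fisher's exact test). None lay near an rRNA gene, which allows a share of up to 0.650% by the exact interval. With the strongest peaks of replicate 1 alone, miRNA genes also passed (adjusted p = 0.0131, Fisher's exact test).

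**Figure D1:**
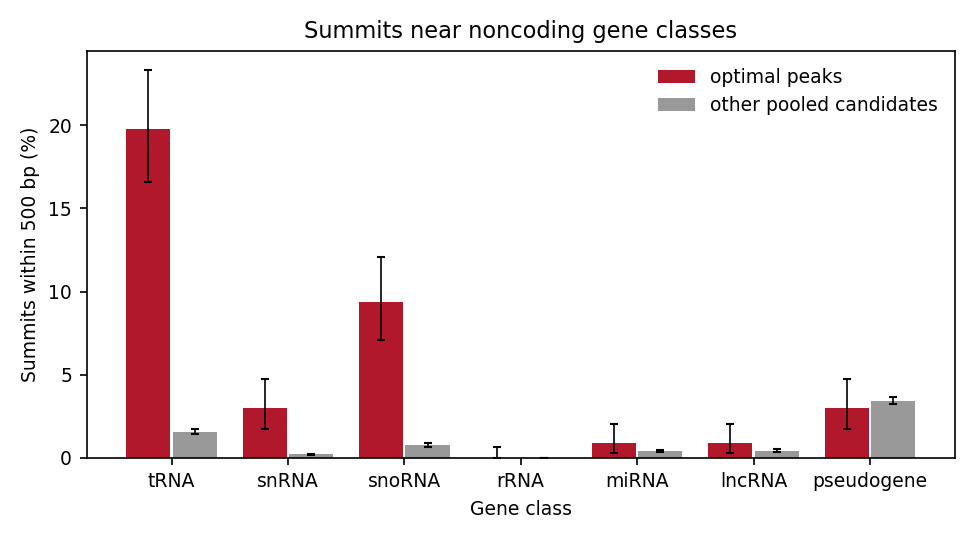
Share of summits (y axis, percent) within 500 bp of a gene of each noncoding class (x axis), for the 566 optimal peaks and the 29434 other pooled candidates, with 95% exact binomial intervals as error bars. The optimal share is 19.8% for tRNA, 9.36% for snoRNA and 3.004% for snRNA genes, against 1.58%, 0.764% and 0.2004% of other candidates.

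An optimal summit lay within 500 bp of 127 of 612 tRNA genes (20.8%, interval 17.6 to 24.2%), 54 of 346 snoRNA genes (15.6%, interval 11.9 to 19.9%) and 16 snRNA genes (12.4% of those annotated, interval 7.26 to 19.4%). At tRNA genes the summit lay a median of 19 bp downstream of the gene's 5' end (quartiles -26 and 59 bp) and inside the gene for 59 of 127. At snoRNA genes it lay upstream of the 5' end for 36 of 54, with a median of -26 bp. At the 16 snRNA genes the median was 163.5 bp downstream of the 5' end (quartiles 43.75 and 212.75 bp), with the summit upstream for 3 and inside the gene for 4. Spliced leader RNA genes are among these 16, and genes close together can share a summit. The share of summits near any of these 3 classes was 44% (interval 34.1 to 54.3%) in ranks 1 to 100, 21.2% (interval 12.1 to 33.02%) in ranks 501 to 566 and 1.55% (interval 1.38 to 1.73%) in ranks 10001 to 30000.

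**Figure D2:**
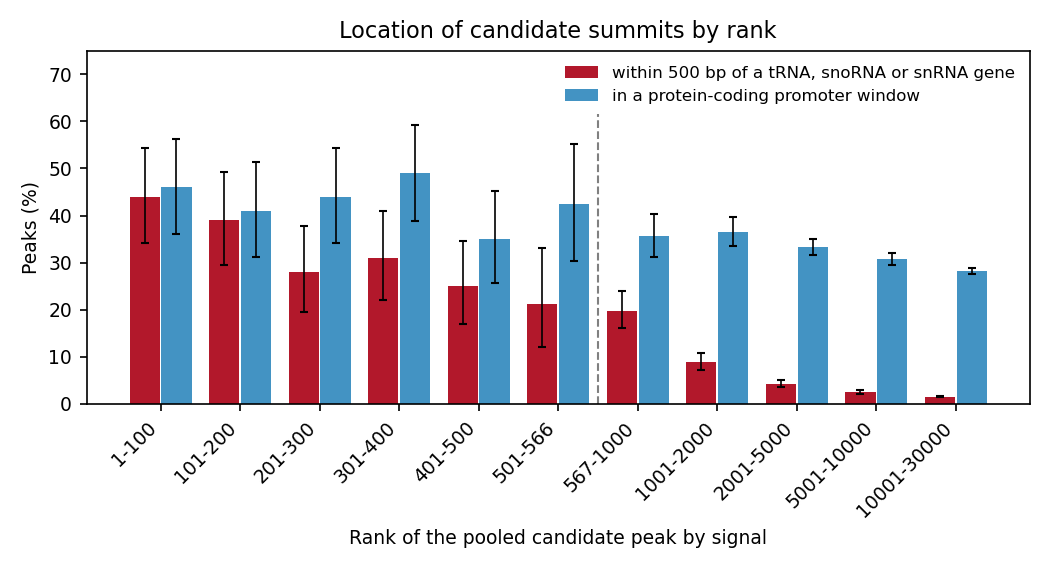
Share of pooled candidate summits (y axis, percent) near a tRNA, snoRNA or snRNA gene and in a protein-coding promoter window, by rank of the signal (x axis), with 95% exact binomial intervals as error bars and a dashed line at the end of the optimal list. The short noncoding share is 44% in ranks 1 to 100 and 1.55% in ranks 10001 to 30000, while the promoter share is 46% and 28.2%.

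Protein-coding promoters also held more of the optimal summits. The window from 1000 bp upstream to 200 bp downstream of a protein-coding start site held 243 of 566 optimal summits (42.9%, interval 38.8 to 47.1%) and 29.6% of the other candidates (odds ratio 1.79, p = 3.28e-11, two-sided Fisher's exact test). Without the peaks near tRNA, snoRNA and snRNA genes, a comparison chosen after the data were seen, the shares were 49.4% and 29.5% (odds ratio 2.32, p = 6.24e-16, Fisher's exact test). By position in gene models, a comparison not fixed beforehand, 51.2% of optimal summits were intergenic against 29.4% of other candidates. Coding exons held 16.1% against 34.7%, introns 23.9% against 29.7%, 5' UTRs 3.36% against 2.07% and 3' UTRs 5.48% against 4.13%. The intergenic, coding exon and intron differences passed adjustment over the 5 classes (adjusted p = 3.99e-26, 3.10e-22 and 0.00413, Fisher's exact tests), and those of the UTRs did not (0.0639 and 0.111).

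The X chromosome held 18.6% (interval 15.4 to 22.003%) of optimal peaks and 17.6% of the other candidates (odds ratio 1.07, p = 0.540, two-sided Fisher's exact test). The direction turned with the strongest peaks of a single replicate, of which X held 16.4% in replicate 2 and 17.3% in replicate 1. It also turned without peaks near tRNA, snoRNA and snRNA genes, where X held 11.2% of optimal peaks and 17.3% of others (odds ratio 0.600, p = 0.00108, Fisher's exact test, chosen after the data were seen).

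Among 34 gene lists, chromatin regulators, heat shock and chaperone genes, and ribosomal protein genes held more promoters with an optimal summit than the background. This background was the 7186 protein-coding genes with any pooled candidate summit in the promoter window, of which 296 had an optimal one. Chromatin regulators had 9 of 47 against 1.94 expected (odds ratio 5.65, interval 2.38 to 12.04, adjusted p = 0.00352, two-sided Fisher's exact test). By signal they were led by set-16, a histone methyltransferase gene (200.9), cbp-1, the homologue of the acetyltransferases CBP and p300 (128.9), lin-9 (115.4), hda-11 (111), lin-54 (109) and jmjd-4 (107). Heat shock and chaperone genes had 7 of 41 against 1.69 expected (odds ratio 4.88, interval 1.81 to 11.3, adjusted p = 0.0214, Fisher's exact test). They were led by dnj-13 (209), hsp-60 of the mitochondrial chaperonin (180), hsp-90 (148), cct-8 of the cytosolic chaperonin (134), hsp-110 (133) and hsp-1 (131). Ribosomal protein genes had 8 of 58 against 2.39 expected (odds ratio 3.8, interval 1.54 to 8.17, adjusted p = 0.0272, Fisher's exact test), led by rpl-3 (294), rps-26 (220), rpl-15 (186), rpl-20 (158), rps-1 (135) and rpl-35 (131). Some peaks lay in the promoter windows of genes of 2 lists, such as the peak shared by lin-54 and rpl-12. The chromatin call was lost without replicate 1 (odds ratio 2.90, adjusted p = 0.318, Fisher's exact test) and without replicate 2 (odds ratio 3.42, adjusted p = 0.141, Fisher's exact test). The chaperone call was lost without replicate 2 (odds ratio 3.42, adjusted p = 0.186, Fisher's exact test), with the window of 2000 bp upstream to 500 bp downstream (odds ratio 3.37, adjusted p = 0.0658, Fisher's exact test) and with the nearest start site (odds ratio 2.19, adjusted p = 0.441, Fisher's exact test). Against the strongest other candidates, a smaller background, the ribosomal odds ratio was 1.93 (interval 0.694 to 4.99, adjusted p = 0.750, Fisher's exact test) and that of chaperones 3.39 (interval 1.005 to 11.4, adjusted p = 0.307, Fisher's exact test). The chromatin call held there (odds ratio 6.16, adjusted p = 0.0273, Fisher's exact test).

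Oxidative phosphorylation genes had 5 of 35 with an optimal summit, cox-5A, cox-5B, cox-6A and mev-1 among them (odds ratio 3.93, adjusted p = 0.115, Fisher's exact test), and did not pass. They passed without replicate 2 (adjusted p = 0.0312, Fisher's exact test), with the 2000 bp window (0.0211) and against all protein-coding genes (0.00433). None of the 45 homeobox genes in the background had an optimal summit in its promoter window, with 1.85 expected (adjusted p = 0.947, Fisher's exact test). Synaptic genes had 0 of 17 (0.700 expected), ligand-gated ion channels 0 of 32 (1.32 expected) and axon guidance genes 0 of 28 (1.15 expected), each with an adjusted p of 1 by Fisher's exact test. With so few expected, these counts do not show that such genes lack peaks. Chemoreceptor genes had 5 of 211 against 8.69 expected (adjusted p = 0.947, Fisher's exact test), led by sre-23, srh-269, srh-2 and sri-5. They held fewer than expected against all protein-coding genes (5 against 19.2, adjusted p = 0.00154, Fisher's exact test) and with the nearest start site (7 against 20.7, adjusted p = 0.00920). Ciliary genes had 3 of 30, which were tmem-107, kap-1 and osm-3 (adjusted p = 0.845, Fisher's exact test).

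**Figure D3:**
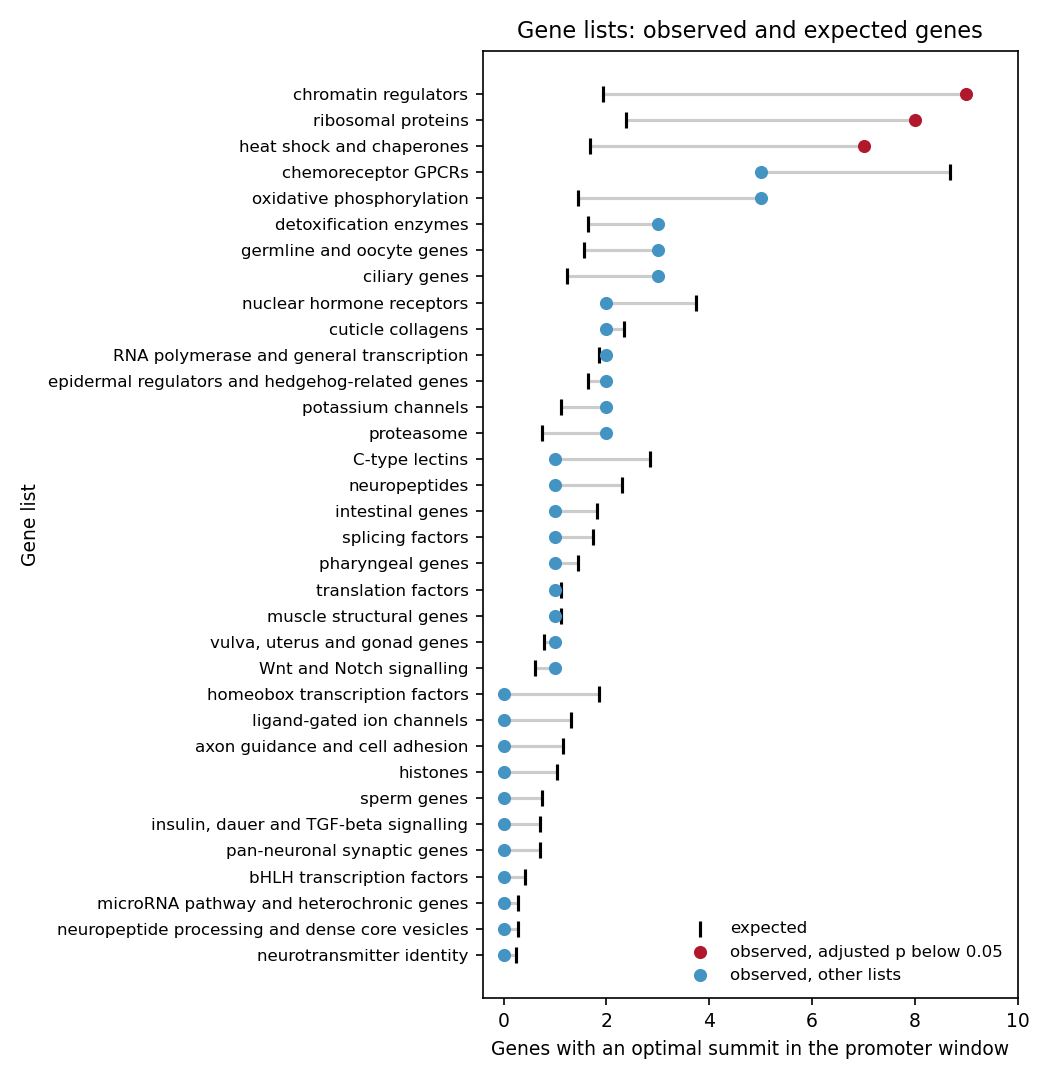
Genes with an optimal summit in the promoter window (x axis, number of genes) for each of 34 gene lists (y axis), as points, with the number expected from the 7186 background genes as a vertical tick. Red points mark chromatin regulators (9 genes, 1.94 expected), ribosomal proteins (8 genes, 2.39 expected) and heat shock and chaperones (7 genes, 1.69 expected).

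Words of 6 bases were compared between a window around each optimal summit and flanks on each side of it. Of 2080 words, 216 were more frequent at the summit and 131 less frequent at an adjusted p under 0.05 (two-sided exact McNemar tests). The 10 with the lowest p among the higher words were AGAGCG, GAACCC, CGAACC, CCTGCG, GTTCGA, CTCTAC, CTGCGC, ACCACT, CGCGCA and AGCGCG. GTTCGA, a core of the box B promoter element inside tRNA genes, was present at 77 summits (13.6%) and in the flanks of 21 peaks (3.71%, adjusted p = 4.61e-07, exact McNemar test). Away from tRNA, snoRNA and snRNA genes it was found only at the summit in 17 peaks and only in the flanks in 10 (adjusted p = 0.652, exact McNemar test). Other words fixed beforehand and higher at the summit were GTTGCC (adjusted p = 0.00714), TTGCGC (0.0185), GAGAGA (0.0246) and GGGCGG (0.0265, exact McNemar tests). Of these only GTTGCC passed away from short noncoding genes (adjusted p = 0.00885, exact McNemar test). There it was only at the summit in 20 peaks and only in the flanks in 2. Against GC-matched promoter candidates none of them passed (lowest adjusted p = 0.554, Fisher's exact test). Lower were TTTCAG, AAAAAA, GAATTC, TGATAA and GATAAG. None of the 7 homeodomain words was more frequent at the summit. Against the flanks 4 were less frequent, such as TAATTA at 8 summits and in the flanks of 27 peaks (adjusted p = 0.0140, exact McNemar test), as were A/T-rich words such as AAAATA and AAAAAT. Against promoter candidates matched for GC content 0 of the 7 were less frequent (TAATTA odds ratio 0.574, adjusted p = 0.579, Fisher's exact test), and 0 were in the 283 strongest peaks or away from short noncoding genes. Against the flanks 1 was less frequent without replicate 1, 3 without replicate 2 and 1 in the 51 bp window. Without replicate 1 the counts were 122 higher and 83 lower, and away from short noncoding genes 39 and 40. Without replicate 2, 127 words were higher. Fisher's exact tests against promoter candidates matched for GC content, which differ in form from the paired tests, called 58 words higher and 19 lower. Summit windows of optimal peaks had a mean GC content of 46.9% ± 9.21 (SD over 566 peaks), against 41.5% ± 8.97 (SD over 29434) in other candidates.

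The strain carried an integrated ceh-79 transgene in an unc-119 mutant background, so both loci were examined. No optimal peak lay within 20 kb of ceh-79 (V, 13301833 to 13304785) or of unc-119 (III, 10902641 to 10908935). Near ceh-79 lay 3 pooled candidates, the strongest at rank 5309, and 3.86% of 10000 random protein-coding genes had as few or fewer. Within 10 kb that share was 12.9%, with 2 candidates, and within 50 kb it was 1.28%, with 10. In the replicate lists, 14 candidates of replicate 1 (3.68%) and 20 of replicate 2 (13.3%) lay within 50 kb. Near unc-119 lay 14 pooled candidates, the strongest at rank 1336, and 61.9% of random genes had as many or fewer.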

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

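Settings that left out peaks near short noncoding genes, added the unspecified noncoding class, or set noncoding classes against the strongest other candidates were chosen after the data were seen. Of 110 alternative values, 83 kept their direction and side of the threshold or stayed close in size. The tRNA, snoRNA and snRNA excesses and the promoter excess passed under each alternative run, but against the strongest other candidates the odds ratios fell from 15.4 to 3.59 for tRNA, from 13.4 to 6.12 for snoRNA and from 15.4 to 5.12 for snRNA genes, and without replicate 1 the odds ratio for snRNA genes was 8.21. Against the strongest other candidates, 34.8% of them in a promoter window, the promoter odds ratio fell from 1.79 to 1.41 (p = 0.000321, Fisher's exact test). Against random genomic positions, 26.1% of them in a window, it was 2.13. In the order tRNA, snoRNA and snRNA, the odds ratios were 20.5, 25.1 and 20.5 within 100 bp and 12.7, 8.70 and 11.4 within 1000 bp. In the 283 strongest peaks they were 15.1, 21.4 and 20.1. The X share, which did not pass the test over all peaks (p = 0.540, Fisher's exact test), lay between 16.4 and 17.3% without one replicate, below the other candidates, and at 11.2% without peaks near short noncoding genes, where it was lower than in other candidates (p = 0.00108, Fisher's exact test). The replicate correlation over optimal peaks, which were those with the highest pooled signal, was -0.165 with -log10 q, and the cause was not tested. Replicate overlap was 54, 431 and 1894 for the 100, 1000 and 5000 strongest peaks, and the discovery rate fit called 601 peaks at 0.01, by construction of list sizes and threshold. The 283 strongest optimal peaks are fewer by construction. Against the strongest other candidates 1 gene list passed in place of 3, and against all protein-coding genes 5 passed, 4 with more genes than expected and 1, chemoreceptors, with fewer. With the nearest start site 2 lists were higher and chemoreceptors again lower. In place of 216 words higher at the summit there were 81 in the 283 strongest peaks, 122 to 127 without one replicate, 69 in the 51 bp window, 58 by Fisher's exact tests against GC-matched promoter candidates and 39 away from short noncoding genes. Fewer peaks entered the first and last of these settings, and for the others the cause was not tested. Candidates near ceh-79 numbered 10 within 50 kb, and those near unc-119 7 within 10 kb and 29 within 50 kb, as the window changed. Unknown read depth limits any statement about peaks below the candidate lists.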

Other observations

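The tests on isotypes, on tRNA genes of X, on the unspecified noncoding class, on homeodomain words away from short noncoding genes and on distinct tRNA genes were chosen after the data were seen. Of tRNA genes on X, 71 of 276 (25.7%, interval 20.7 to 31.3%) had an optimal summit within 500 bp, against 56 of 336 on autosomes (16.7%, interval 12.8 to 21.1%, odds ratio 1.73, p = 0.00680, two-sided Fisher's exact test). By isotype, 13 of 34 alanine tRNA genes, 6 of 13 cysteine tRNA genes and 0 of 19 tyrosine tRNA genes had one, and no isotype passed adjustment (lowest adjusted p = 0.207, Fisher's exact test). The annotation's unspecified noncoding class lay within 500 bp of 151 optimal summits (26.7%, odds ratio 3.55, adjusted p = 1.52e-31, Fisher's exact test), of which 100 also lay near a tRNA, snoRNA or snRNA gene. Without peaks near those genes the odds ratio was 1.71 (51 of 385 summits, p = 0.000745, Fisher's exact test).

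Optimal peaks lay near tRNA, snoRNA and snRNA genes, and 3 technical explanations were weighed. Reads shared between near-identical copies are argued against as the whole cause at snoRNA genes, since distinct tRNA and snoRNA genes had an odds ratio of 12.8 (interval 9.14 to 17.6), and the 51 optimal summits behind it were at snoRNA genes. For tRNA genes this stays open, because 0 optimal summits lay near the 21 distinct ones and the odds ratio could reach 18.8, and copies of snRNA genes were not tested. Base composition is argued against as the whole cause, with an odds ratio of 16.0 (interval 13.1 to 19.5) within GC deciles against 18.2 without them. Pull-down of highly transcribed loci whatever the tagged protein may contribute. Away from these genes the union of 4 lists had 18 of 151 promoters with an optimal summit (odds ratio 4.18, interval 2.36 to 7.02, p = 2.27e-06, Fisher's exact test). They were 7 ribosomal, 7 chaperone, 4 respiratory and 0 of 26 translation factor genes. The list tests over all optimal peaks had already counted these genes, so the union is not separate support for this explanation. Chromatin regulators, outside that union, had 9 of 45 in the same setting (odds ratio 7.52, adjusted p = 0.000452, Fisher's exact test). The excess was therefore not particular to these 4 lists and does not single out transcription level. Over all optimal peaks, the ribosomal and chaperone excesses did not pass against the strongest other candidates. No biological explanation was tested.

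Homeodomain words were not more frequent at optimal summits than in the flanks. Base composition as what hides them stays open: against GC-matched promoter candidates 0 of the 7 words were higher or lower, but their odds ratios ran from 0.574 to 1.46, so the median of 0.939 decides nothing. Dilution by peaks at short noncoding genes stays open too. Away from them 0 of the 7 were higher and the median ratio of peaks with the word only at the summit to only in the flanks was 0.50. In that comparison the A/T word AAAAAA was also rarer at the summit (46 peaks only there, 118 only in the flanks). Base composition could therefore lower the ratio with or without dilution, and the comparison cannot decide. Whether CEH-79 binds these particular words is unknown here, and no biological explanation was tested.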
